A study of Mus musculus with 2 samples.

How the data were processed

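Gene expression was measured in 2 samples of total RNA from ATDC5 cells, 1 labelled as overexpressing GFP and 1 as overexpressing HES1. Per the labels' protocols, each RNA was taken after 3 days in monolayer on 60 mm dishes, and Cy3-labelled cRNA was made from 0.1 µg of it. Per the file headers, both arrays were of 1 Agilent mouse design with 1 colour, annotated on the mm9 build. The scanner images were read with Agilent Feature Extraction 10.10.1.1, per the file headers and the submitters' processing notes. Both arrays lay on the same slide, per the file headers, so the slide did not separate the groups, but each group held a single array position. The number of arrays limits the precision.

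The scanner files hold an intensity per spot, with no scaling between arrays, per the file headers. The processed signal is that intensity after the scanner software's background correction and detrending, per the file headers. The deposited value table holds an intensity per spot on a linear scale. Set against the scanner files, it equalled the processed signal times 1 factor per array, 1.45 for GFP and 1.53 for HES1. Those factors gave both arrays a 75th percentile of 1057.2, with medians of 67.7 and 76.6. Its scale, direction and lack of centring are therefore known, and it repeats the scaling used here.

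The main value was log2 of the processed signal minus each array's 75th percentile over the 59305 spots that are not controls. A spot with an outlier flag on either array was left out (1053 spots), and no spot was saturated. Spots of a probe were averaged, which left 54948 of 55681 probes. Printed signals are these values on the linear scale with the 75th percentile set to 1057.2. A probe was well above background on an array where most of its kept spots carried that scanner flag. Accessions in the files were named through a RefSeq gene table of mouse assembly GRCm38.p6, which was used for names only. A symbol was found for 26869 probes (48.9%), covering 20433 genes, and 28079 probes stayed unnamed. No probe had several symbols. A gene was represented by its brightest probe among those well above background on at least 1 array. Of 3718 genes with more than 1 such probe, 3 had probes at least 2-fold apart from 0 in opposite directions.

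With 1 array per group no test was run. A gene counted as higher or lower at a measured log2 difference of 1 or more in size. Where its probe was well above background on 1 array, the text gives a bound. The bound sets the bright signal against the dim probe's own signal or the lowest signal well above background on that array (38.1 for GFP and 39.0 for HES1), whichever was higher. Counts by bounds use the bound of such a gene in place of its measured difference. No fold is given where both signals were below background or the bound was under 1. A gene list was described by the median log2 difference of its measured genes and its percentile among 10000 random lists of the same size matched on deciles of mean signal. This describes these arrays and is not a p-value. There were 27 gene lists and 10 cell type lists. Technical precision came from 2 sources. The scanner's error model gave a median error of 0.20 for a gene's log2 difference. The 235 replicated probes with at least 8 kept spots that were well above background on both arrays had a median SD between spots of 0.07, with a 90th percentile of 0.14. Neither includes differences between cultures. The 8 detected spike-in controls differed between arrays by -0.08 to 0.10 on the log2 scale.

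Groups, gene lists, the rule for named genes and most alternatives were set before the data were examined. The named genes were Hes1, the 12 highest and 12 lowest differences among symbols measured on both arrays, the 3 highest bounds each way among genes on 1 array, and up to 4 members past 2-fold per list (or the single largest). A fixed set joined them: Adamts5, Mmp13, Il6, Il1rl1, Camk2a, Camk2b, Camk2d, Camk2g, Col2a1, Acan, Sox9, Col10a1, Runx2, Notch1, Jag1, Rbpj, Actb and Gapdh. Members that repeat a list's count were left out, and some named genes are not reported here. Genes named outside this rule were chosen after their values were seen. They are Mcm2 to Mcm7, Pcna, Vegfa, Rpl35, Ifit3, Lyz2, Tyrobp, Laptm5, Cd14, Csf1r and Ptprc. Bglap2, Alpl, Spry1, Dusp7, Dkk1, Ccn4 and those of the added groups in the closing section also belong to them.

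The alternatives were quantile normalization, scaling on the median of probes seen on both arrays, a loess fit of the difference on mean signal (span 0.3), the authors' deposited values, other filters on dim probes, the median over a gene's probes, outlier spots kept, saturated spots left out, and thresholds of 1.5-fold and 3-fold. A normexp background correction (offset 50) with quantile normalization had been planned on mean spot signals, which the files used here do not hold. It was run on the median spot and background signals instead, a choice made after seeing the data, as were scaling on the spike-ins and counting by bounds. The authors' values repeat the main scaling and are not counted among the 5 other normalizations. The functions were tested on simulated data for this comparison over 14273 genes, with noise of the scanner's error and 200 genes moved. The 2-fold rule recovered 99% of changes of 1.5 on the log2 scale and 100% of changes of 2.5, with 0 unmoved genes past 2-fold. Every spot was given the same noise, the median error of 0.20, so this 0 was all but fixed in advance. The scanner's error was larger for dim genes, such as 0.82 for Mmp13, and no differences between cultures were simulated. The simulation therefore checks the functions and does not give a rate of false calls in the data. A list of 40 genes shifted by 0.3 reached the 100th percentile, and 6 of 100 unshifted lists fell outside the middle 95%. The simulated noise was independent between genes, and the measured log2 differences had an SD of 1.11 over all genes. These list results therefore check the functions only as well. The work used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.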

Results

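The study compared 2 stable lines of ATDC5 cells, a mouse chondrocyte cell line, made by lentiviral transduction. One line was labelled as overexpressing GFP, a fluorescent protein that served as the control. The other was labelled as overexpressing HES1, a transcriptional repressor that acts downstream of Notch receptors. Both lines had been grown for 3 days as monolayers in 60 mm dishes. Total RNA from each line was hybridised to 1 single-colour Agilent whole-genome mouse array, so the design asked how gene expression differed between the HES1 line and the GFP line. With 1 array per group there were no replicates, and no difference below has a replicate check or a p-value. A group was therefore described by size: a gene counted as higher or lower where its 2 measured signals differed at least 2-fold. A gene not well above background on 1 array was counted the same way, while its fold is given as a lower bound, and where bounds change a list's count the count by bounds follows it. The arrays were alike in depth of detection, with 54.6% of the spots well above background on the GFP array and 56.6% on the HES1 array. Of 20433 genes with a symbol on the array, 14273 were well above background on at least 1 array and 13073 on both. Signals are given in scanner units after both arrays were set to the same 75th percentile of 1057.2, and can be compared between arrays for a gene but not between genes. The scanner software's own error put the technical uncertainty of a gene's log2 difference at a median of 0.20.

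The overexpressed gene itself could not be followed on these arrays. The single probe for mouse Hes1 was not well above background on either array, with scaled signals of 10.2 on the GFP array and 10.3 on the HES1 array, so no fold is given. The labels do not say from which species or which part of the gene the transgene was made, and a transgene that lacks the sequence the probe matches would not be seen. The probe therefore checked neither label, and the samples are called here the sample labelled HES1 and the sample labelled GFP. In a list of HES, HEY and related transcription factors, 7 were measured and 0 were past 2-fold by bounds. Hey2 was not well above background in the GFP sample and at least 1.62-fold higher in the sample labelled HES1.

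The samples differed most in genes of the antiviral interferon response. Across all genes, 1582 were at least 2-fold higher in the sample labelled HES1 and 707 at least 2-fold lower. These counts were 850 and 339 under a normexp background correction of median spot signals with quantile normalization. They were 1354 and 638 by bounds, and 920 and 577 where a gene had to be well above background on both arrays. All 32 measured members of the interferon-stimulated gene list were at least 2-fold higher, with a median log2 difference of 6.12. That median lay above all of 10000 random gene lists matched on signal, whose middle 95% ran from -0.28 to 0.06. Oas1a, one of the enzymes that make 2',5'-oligoadenylate on sensing double-stranded RNA, went from 118 in the GFP sample to 232609 in the sample labelled HES1, a 1971-fold difference. Rsad2, which encodes the antiviral protein viperin, was 499-fold higher, and Ifi44 was 540-fold higher. Irf7, the transcription factor that amplifies interferon transcription, was 477-fold higher at 25160 against 52.8. Oas2 was not well above background in the GFP sample and at least 2092-fold higher in the sample labelled HES1. The smallest difference in the list, 2.23 on the log2 scale, was that of B2m, the light chain of MHC class I molecules.

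**Figure D1:**
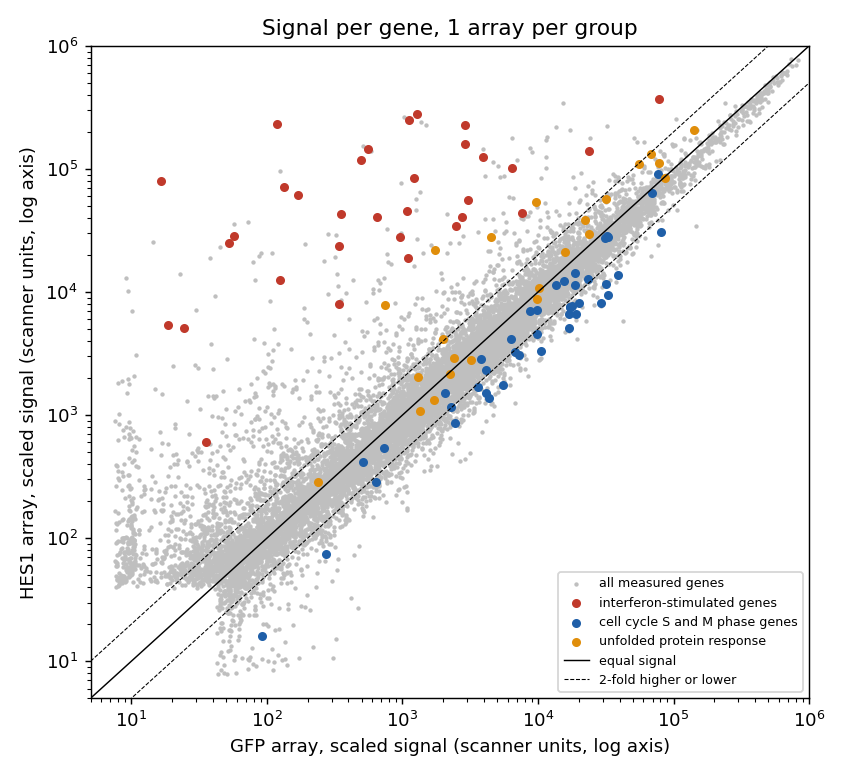
Scaled signal of each of 14273 measured genes on the GFP array (horizontal, log axis) and the HES1 array (vertical, log axis), in scanner units; each point is a gene on 1 array per group, coloured points mark 3 gene lists, the solid line marks equal signal and the dashed lines a 2-fold difference. All 32 interferon-stimulated genes lie above the upper dashed line, and 24 of 43 S and M phase genes lie below the lower one.

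The 12 largest differences among genes measured on both arrays were all higher in the sample labelled HES1, and 6 of them belong to the interferon-stimulated list. Besides Oas1a, Ifi44, Rsad2 and Irf7, they were Oas1f (768-fold), Ifi207 (631-fold), Phf11d (507-fold), Oasl1 (362-fold), Tgtp2 (303-fold), Oasl2 (265-fold), Cxcl10 (254-fold) and Ifit3b (240-fold). A second Ifit3b probe gave a log2 difference of 5.69 against 7.91, and second probes of Oas1a, Ifi207 and Tgtp2 were not well above background in the GFP sample. Several of these have near-identical paralogs, such as Oas1a and Oas1f or Ifit3 and Ifit3b, and a probe may read more than 1 of them. Vgf, which encodes a secreted neuropeptide precursor, was at least 669-fold higher, and Phf11a at least 494-fold higher; neither was well above background in the GFP sample. Differences in the other direction were smaller. At 16-fold or more, 108 genes measured on both arrays were higher and 0 were lower.

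A list of cytokines, chemokines, their receptors and related inflammatory genes was also higher in the sample labelled HES1. Of 41 measured, 22 were at least 2-fold higher, 0 lower and 19 within 2-fold, with a median of 1.09, above all of the matched random lists. The median was 0.56 under the normexp correction and 0.57 without a filter on dim probes. Cxcl10 is a chemokine that interferon induces, and it went from 1035 to 262774. Il6, the inflammatory cytokine interleukin 6, was 225-fold higher at 19729 against 87.5. Ccl2, a chemokine that draws monocytes, was 42.0-fold higher, and its 10 spots per array left a technical error of 0.06 on its log2 difference of 5.39. Il15 was at least 63.5-fold higher. Il1rl1, the receptor for interleukin 33, was 7.99-fold higher at 5483 against 686, and its second probe gave a log2 difference of 2.57.

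A list of calmodulins, the kinases they activate and calcineurin pathway genes stayed within the range of random lists. Of 23 measured members of that list, 1 was at least 2-fold higher and 3 at least 2-fold lower, and the median of -0.24 stood at the 10.07th percentile of random lists. The member that was higher was Camk2b, the beta subunit of calcium/calmodulin-dependent kinase II, at 1161 against 101 (11.5-fold). A second Camk2b probe was not well above background on either array (27.7 in the GFP sample and 46.8 in the sample labelled HES1). The other subunits of that kinase lay within 2-fold, with log2 differences of 0.30 for Camk2d, 0.20 for Camk2g and 0.41 for Camk2a. A second Camk2a probe was not well above background in the sample labelled HES1 (42.7 and 16.7). Rcan2, an inhibitor of the calmodulin-dependent phosphatase calcineurin, was 4.66-fold lower. Calm3, 1 of the calmodulin genes, was 2.25-fold lower and Nfatc1 2.05-fold lower.

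Proteases that degrade cartilage matrix went different ways. Of 29 measured matrix proteases, 7 were at least 2-fold higher and 2 lower, with a median of 0.12 at the 84.3th percentile. Mmp13, the collagenase of hypertrophic cartilage, was not well above background in the GFP sample and was at least 3.49-fold higher in the sample labelled HES1. Adamts5, the main aggrecanase of mouse cartilage, had signals of 199 and 221, a log2 difference of 0.15 that lay within the technical error of 0.22, and its second probe gave 0.32. Mmp9 was 4.11-fold higher and Adamts6 4.67-fold higher. Adamts17 was 2.68-fold lower by its brightest probe, while its other probe was not well above background in the GFP sample (25.6 and 52.5). Of 12 protease inhibitors, 1 was at least 2-fold higher and 1 lower, with a median of 0.22 at the 93.0th percentile. Serpine2 was 3.94-fold lower.

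**Figure D2:**
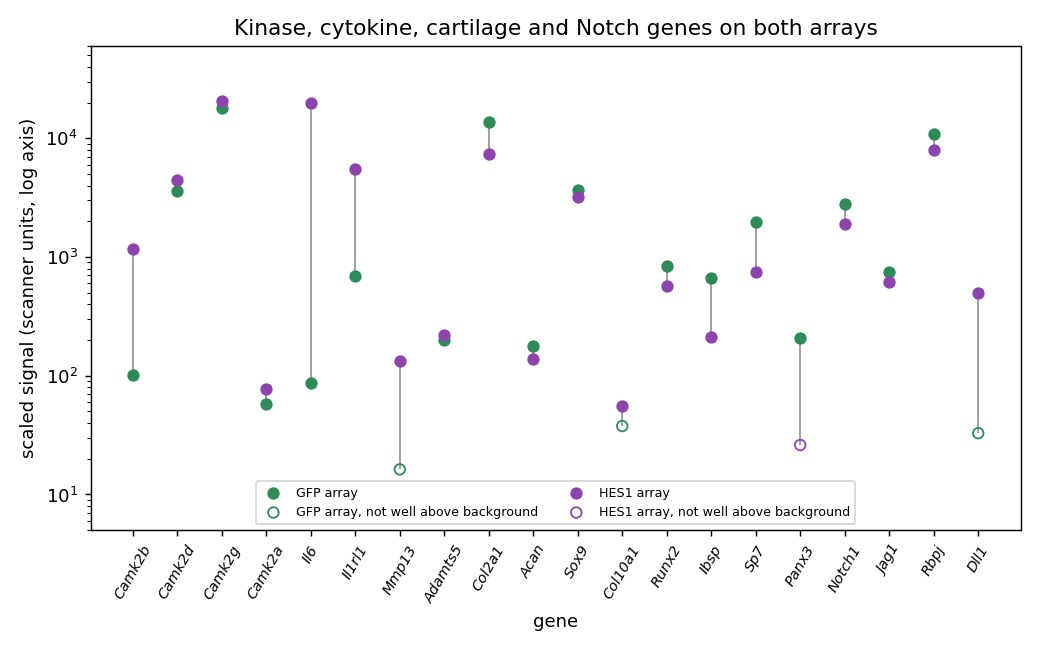
Scaled signals (log axis, scanner units) of 20 genes on the GFP array (green) and the HES1 array (purple), 1 array each; open circles mark a probe that was not well above background there, and heights can be compared within a gene only. Camk2b, Il6, Il1rl1, Mmp13 and Dll1 were higher on the HES1 array, Ibsp, Sp7 and Panx3 were lower, and Adamts5 and Sox9 were nearly level.

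Genes of hypertrophic and mineralizing chondrocytes were lower as a list in the sample labelled HES1. Of 23 measured, 7 were at least 2-fold lower, 2 higher and 14 within 2-fold, and the median of -0.77 lay below all of the matched random lists. With genes seen on 1 array set to their bound the median was -0.71. Panx3, a channel protein of differentiating chondrocytes and osteoblasts, was at least 5.31-fold lower. Ibsp, which encodes bone sialoprotein, was 3.16-fold lower, and Sp7, the transcription factor osterix, was 2.65-fold lower at 742 against 1968. The 2 members that were higher were Mmp13 and the angiogenic factor Vegfa, at 1.02 on the log2 scale. Runx2, a master regulator of hypertrophy and bone formation, had a log2 difference of -0.55, and of -0.09 by its second probe. Col10a1, the collagen of hypertrophic cartilage, was not well above background in the GFP sample and at least 1.45-fold higher in the sample labelled HES1 (37.7 and 55.2).

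The cartilage matrix list had a median of -0.22 over 21 measured genes, at the 5.66th percentile and inside the middle 95% of random lists. After a loess fit its median was -0.18 at the 1.92th percentile, below that range. In it 4 genes were lower (3 by bounds) and 1 higher. Ucma, a secreted protein of early chondrocytes, was 2.56-fold lower and Cytl1 2.36-fold lower. Sox6 was at least 1.48-fold lower, and Col9a3, a chain of type IX collagen, at least 7.07-fold higher. Sox9, the transcription factor that specifies chondrocytes, had signals of 3683 and 3227 (log2 difference -0.19). Col2a1, the main cartilage collagen, went from 13796 to 7379, a difference of -0.90 that stayed within 2-fold, and Acan, which encodes aggrecan, had a difference of -0.37. General matrix genes had a median of -0.01 over 44 measured genes, at the 91.1th percentile, with 4 higher and 3 lower (2 by bounds). Col5a3, a chain of type V collagen, was at least 33.9-fold higher, while the elastic fibre gene Fbn2 was 4.70-fold lower. Of 24 integrin and adhesion genes, 3 were higher (2 by bounds) and 2 lower (median 0.05, 86.2th percentile). Vcam1 was 6.52-fold higher and Itga11 2.81-fold lower.

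Notch pathway genes had a median of -0.26 over 30 measured genes, at the 2.20th percentile of random lists, with 4 lower (2 by bounds) and 2 higher. After a loess fit the median was -0.13 at the 2.12th percentile. Dll1, a Notch ligand, was at least 13.0-fold higher, and Notch3 at least 3.07-fold higher. Lfng, a glycosyltransferase that modifies Notch receptors, was 2.75-fold lower, and Dlk1 at least 1.85-fold lower. The receptor Notch1, the ligand Jag1 and the DNA-binding partner Rbpj lay within 2-fold, with differences of -0.57, -0.26 and -0.46. Of the genes described as repressed by HES1, 7 were measured. Their median was -0.56 at the 1.59th percentile, yet the 2 that passed 2-fold were both higher: Dll1 and Gadd45g, a stress-induced growth arrest gene (3.52-fold). The other 5 lay between -0.97 and -0.55. Without a filter on dim probes the median was 0.0097.

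S and M phase genes were lower as a list in the sample labelled HES1. Of 43 measured, 24 were at least 2-fold lower and 0 higher, and the median of -1.10 lay below all of the matched random lists. Mki67, the proliferation antigen Ki-67, was 3.55-fold lower at 8203 against 29151. Ccnb2, a mitotic cyclin, was 3.48-fold lower, and Aurkb, a kinase of chromosome segregation, was 3.71-fold lower. Cenpf was at least 2.34-fold lower. The replication licensing genes Mcm2 to Mcm7 stayed within 2-fold, from -0.39 for Mcm3 to 0.24 for Mcm6, and the replication clamp Pcna was at -0.13. Among 15 D-type cyclins, their kinases, cyclin-dependent kinase inhibitors and retinoblastoma family genes the median was -0.18 (30.8th percentile), with 2 higher and 2 lower. Ccnd2 was 6.49-fold higher and Cdkn1a, which encodes the inhibitor p21, was 4.48-fold higher, while Cdkn2d was 2.34-fold lower. Of 19 p53 target genes, 5 were higher and 2 lower (median -0.21, 19.3th percentile). Plk2 was 6.83-fold and Gadd45a 4.95-fold higher, whereas the apoptosis effector Perp was 6.26-fold lower.

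Immediate early genes and unfolded protein response genes were higher as lists in the sample labelled HES1. Of 20 immediate early genes, 12 were at least 2-fold higher and 0 lower (median 1.37, above all matched random lists). Fos was 11.9-fold higher, Egr1 11.2-fold and Zfp36 at least 5.41-fold. Of 23 unfolded protein response genes, 5 were higher, 0 lower and 18 within 2-fold, with a median of 0.51 that also lay above all random lists. The 4 largest were Ddit3, which encodes the pro-apoptotic factor CHOP (12.5-fold), Atf3 (10.6-fold), Trib3 (6.26-fold) and Chac1 (5.57-fold). The NRF2 target list did not stand apart (21 measured, median -0.01, 84.9th percentile), but 4 members were higher and 0 lower. They included the cystine transporter Slc7a11 (11.1-fold) and the haem-degrading enzyme Hmox1 (8.51-fold). Of 33 hypoxia and glycolysis genes, 4 were higher and 1 lower (median -0.04, 75.8th percentile), with Hk2 4.14-fold higher. Egln3 was 1 of the 4 by its brightest probe (39.3 in the GFP sample and 125 in the sample labelled HES1). Its other probe went the opposite way (82.0 and 29.0), and each probe was well above background on 1 array only.

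Wnt pathway genes were lower as a list, with a median of -0.40 over 40 measured genes, below all of the matched random lists, and with 8 at least 2-fold lower and 2 higher. Without a filter on dim probes the median was -0.19. Of the members measured on both arrays, Nkd1 (6.21-fold lower) and Lgr5 (5.49-fold lower) were the lowest. Axin2, a feedback target of beta-catenin signalling, was not well above background in the sample labelled HES1 and at least 2.02-fold lower, and its second probe was not well above background on either array. Sfrp1, a secreted Wnt antagonist, was at least 2.69-fold higher. The FGF and hedgehog list had a median of -0.19 over 24 genes (11.3th percentile), with 6 higher (5 by bounds) and 5 lower. Its higher members included Etv5 (5.60-fold) and Dusp6 (4.22-fold), which are outputs of FGF and ERK signalling. Its lower members included Fgf9 (at least 4.06-fold) and the hedgehog effector Gli2 (at least 2.54-fold). Of 36 BMP and TGF-beta genes, 4 were higher and 3 lower (median -0.22, 9.23th percentile). The activin subunit gene Inhbb was 7.37-fold higher, and the BMP antagonist Chrdl2 was 3.75-fold lower.

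The medians of 5 lists on metabolism, housekeeping and HOX genes ran from -0.64 to -0.20. Cholesterol and fatty acid synthesis genes had a median of -0.64 over 29 genes, below all matched random lists, with 1 lower (0 by bounds) and 0 higher. Oxidative phosphorylation genes had a median of -0.31 (32 genes, 0.52th percentile) with 0 past 2-fold, and Ndufa4 was the lowest at -0.96. After the loess fit their median was -0.12, at the 0.99th percentile. The 53 ribosomal protein genes all lay within 2-fold (median -0.20, 22.6th percentile), from Rpl22 at -0.57 to Rpl35 at -0.02. Of 17 reference genes, 1 was past 2-fold, the interferon-stimulated gene B2m (median -0.22, 23.02th percentile). Actb had a difference of -0.27 and Gapdh of -0.11. HOX genes had a median of -0.35 over 27 genes (0.62th percentile), with 6 lower and 1 higher. Their median was -0.20 after loess, -0.19 under normexp and -0.0029 without a filter on dim probes. Hoxc5 was 2.77-fold lower and Hoxc13 4.06-fold higher.

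**Figure D3:**
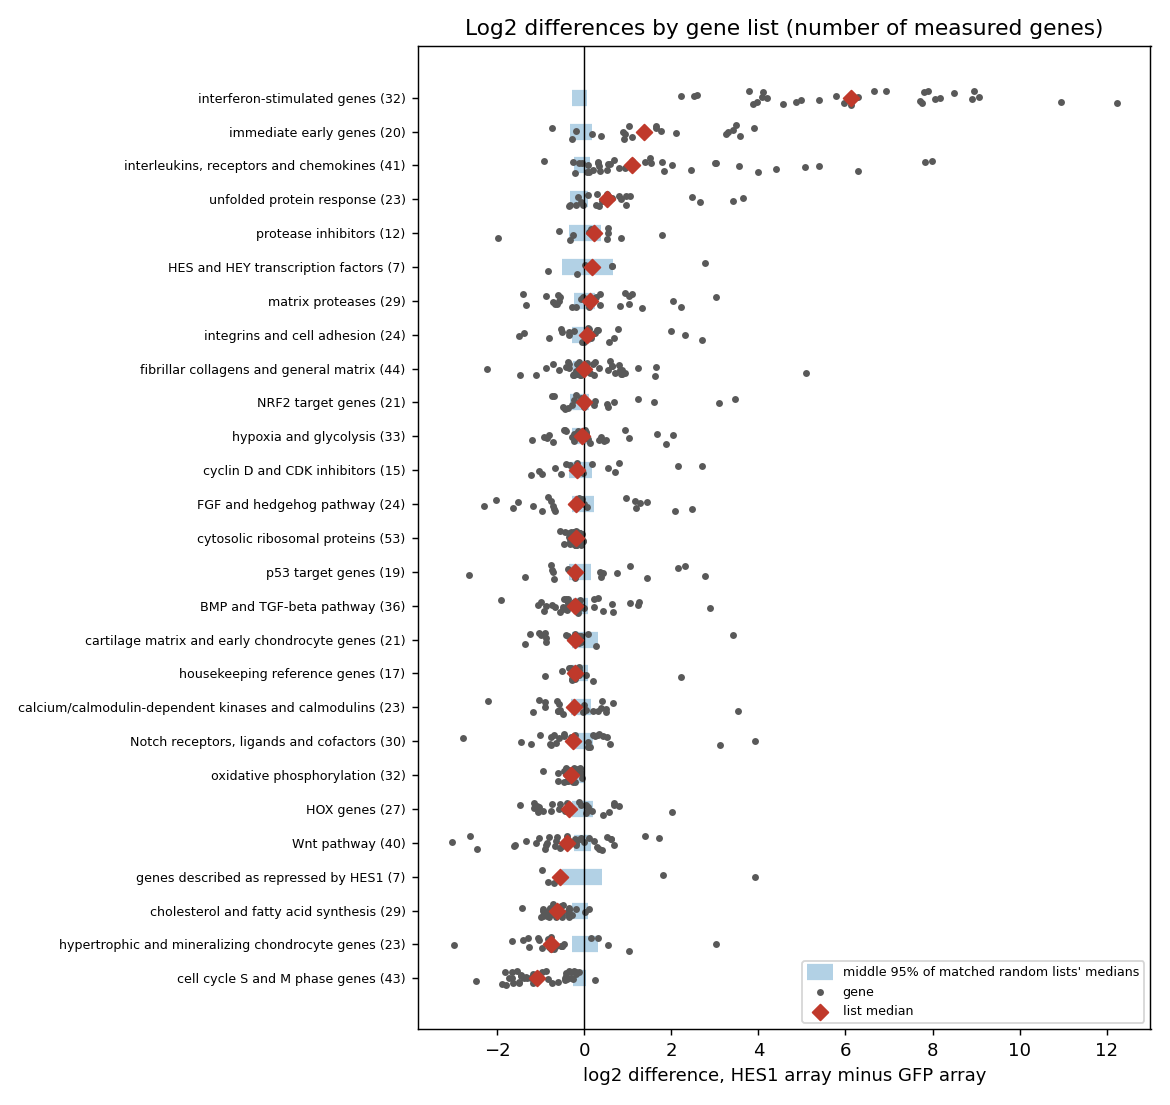
Log2 differences, HES1 array minus GFP array, for the measured genes of 27 gene lists; grey points are genes, red diamonds list medians, and blue bars the middle 95% of the medians of 10000 matched random lists. The interferon-stimulated list stands at 6.12, and the S and M phase list at the bottom at -1.10.

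Markers of other cell types stayed within the range of random lists, apart from osteoblast genes. The 8 osteoblast genes had a median of -0.90 at the 0.03th percentile with 3 at least 2-fold lower. They were Ibsp, Sp7 and Phex, which all belong to the hypertrophic list as well. Bglap2, Alpl and Runx2 are shared with that list too, so this is largely the same result again. Medians of the other 9 cell type lists were -0.19 for adipocyte (6 genes), -0.09 for skeletal muscle (4), -0.21 for smooth muscle (5), -0.02 for tendon (3) and 0.44 for endothelium (5). They were 0.04 for blood and macrophage (5), 0.10 for neuron (9), 0.40 for epithelium (4) and -0.06 for pluripotent cells (8). Random ranges were wide for small lists, such as -0.65 to 1.60 for skeletal muscle and -0.63 to 1.79 for epithelium. A place inside such a range says little. Single members still differed. Scx, the tendon transcription factor, was 3.52-fold lower, Mylk 3.17-fold lower, Vwf 3.51-fold higher and the lymphocyte surface gene Cd52 at least 4.01-fold higher. In all, 13 of the 37 lists lay outside the middle 95% of random lists, where 1.85 would if the genes of a list varied independently. Genes of a list can move together between any 2 cultures, so more than 1.85 could fall outside without an effect of the group. Some lists share genes, so they do not count as independent.

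The 12 largest decreases among genes measured on both arrays ran from 7.23-fold to 4.98-fold. Penk, which encodes the opioid precursor proenkephalin, was the lowest at 5856 against 42312. It was followed by Nrep (6.63-fold), the pro-apoptotic gene Bmf (6.39-fold), Gas7 (6.38-fold), Perp, Nkd1 and the sodium channel gene Scn3a (6.05-fold). The other 5 were Lgr5, Cyp39a1 (5.44-fold), Ankle1 (5.31-fold), Padi2 (5.04-fold) and Kcnmb4 (4.98-fold). Kcnmb4 had a second probe within 2-fold (-0.27), and second probes of Gas7 and Nkd1 were not well above background in the sample labelled HES1. Among genes not well above background in the sample labelled HES1, Lrrc6 was at least 12.2-fold lower, Kmo at least 10.7-fold and Naa11 at least 8.24-fold.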

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

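The tests on normalization, on blood cells and on the transgene for the interferon genes, the tests on scaling and on the interferon response or the transgene for the S and M phase genes, and the test on the Hes1 probe were chosen after the results were seen.

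Probes without a gene symbol, which enter no comparison above, carried signal that differed between the arrays. Of 13350 such probes well above background on at least 1 array, by their measured signals 1195 were at least 2-fold brighter in the sample labelled HES1 than in the GFP control sample, and 1026 were dimmer. Probes named in the files by an mm9 position alone made up 7126 of them. By their measured signals 656 of these were at least 2-fold brighter and 586 dimmer, and 71 were at least 16-fold brighter. A dimmer one, designed to 118291593 to 118324230 on chromosome 9, was at least 15.6-fold dimmer. Some of the largest increases among the probes named by position follow. On chromosome 7, a probe designed to 111526943 to 111545093 went from 8.94 to 8671, at least 227-fold. A probe for the overlapping interval 111530578 to 111539097 was at least 72.0-fold brighter. On chromosome 1, a probe for 175653557 to 175671940 was 546-fold brighter, and a second probe for that interval at least 369-fold. A probe for 87343550 to 87362900 on chromosome 1 was at least 103-fold brighter. Also on chromosome 1, probes for 85036677 to 85038530 and 85117750 to 85129200 were at least 168-fold and at least 89.97-fold brighter. What is annotated at these positions was not analysed here.

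The first pattern weighed was the higher level of every measured interferon-stimulated gene. For normalization between the arrays, the lowest list median over the 5 other normalizations was 5.64. That outcome was all but fixed in advance, because these normalizations kept the median of all genes between -0.07 and 0.08. It shows only that the list's difference did not hang on which of them was used. A local defect of the array is argued against, because 188 spots within 2 positions of the list's 42 spots had a median log2 difference of -0.10. Blood cells or macrophages in the sample are argued against as the whole cause: 10% of the 10 markers on the array were at least 2-fold higher, and the abundant macrophage transcripts Lyz2 (13.1), Tyrobp (16.2) and Laptm5 (25.6) were not well above background in the sample labelled HES1, while Cd14, Csf1r and Itgam were well above background in both samples. Cd52 (10.5 and 153) and Ptprc (25.2 and 47.8) were well above background in the sample labelled HES1 only. The HES1 transgene, a property of this one line such as its transduction or culture, and a wrong label cannot be told apart, because 1 HES1 line was on arrays.

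The second pattern was the lower S and M phase genes. A signal-dependent bias is argued against, as the list's median was still -0.96 after the loess fit. With both arrays scaled on the spike-in controls the list's median was -1.09. That outcome was fixed in advance, because the spike-ins were already known to be level (mean log2 difference -0.01), so it adds no evidence on scaling. Scaling moves all genes alike, and the median of all genes was -0.06, so it leaves the list's low place among the genes as it was. The interferon response, the HES1 transgene, and a property of this one line such as its transduction or culture could each account for it. These and a wrong label cannot be told apart with 1 HES1 line on arrays.

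The third pattern was the Hes1 probe at background in both samples. A faulty or mismatched Hes1 probe, which includes a transgene without the probe's sequence, cannot be told apart from a lack of expression, because 1 probe named Hes1 was on the array.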

How the results depend on the processing

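The normexp correction, spike-in scaling and counting by bounds were chosen after seeing the data. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. Under the 4 other normalizations (without normexp) the number of higher genes ran from 1492 to 1749 and of lower genes from 510 to 786. The authors' values, which repeat the main scaling, gave 1583 and 708. With normexp, which changed the background correction, the spot signal and the normalization together, there were 850 higher and 339 lower, and the cause was not tested. With genes required on both arrays, fewer genes were tested and 920 were higher and 577 lower. Without a filter on dim probes, more genes entered and 2337 were higher and 923 lower. Genes on 1 array set to their bounds gave 1354 higher and 638 lower. The 1.5-fold threshold gave 2480 higher and 2084 lower, and the 3-fold threshold 997 and 178. No spot was saturated, so that setting moved nothing. The loess fit moved the median of all genes from -0.06 to 0.08. Relative to the median of all genes, 35 of the 37 list medians kept their sign under the 3 normalizations that do not move all genes alike (quantile, loess and normexp). The exceptions were ribosomal proteins and pluripotent cells. The cartilage matrix list moved from the 5.66th to the 1.92th percentile after loess. Of 1466 alternative values of 136 named genes, 1358 moved by less than the technical error, 106 by more, and 2 reversed. Many of the small moves, here and for the lists below, were fixed in advance. Leaving out saturated spots, using the authors' values, and scaling on the spike-ins or on the median of shared probes move all genes alike, by little or nothing. Under normexp alone, 82 of the 136 moved by more. The 2 that reversed were Axin2 without a filter on dim probes (0.53, from its probe at background) and Itgam by the median over its probes (0.25, as its dimmer probes differ from the brightest). Of 407 alternative list medians, 296 moved by less than the median SD between spots (0.07), 110 by more, and 1 reversed. Only the 13 lists outside the range of random lists counted as able to reverse. Of the 24 lists inside it, 13 changed sign at least once, in 33 alternative medians. The list of genes described as repressed by HES1 reversed without a filter on dim probes (0.0097), when more genes near background entered. Signals close to background limit the folds of dim genes to bounds.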

Other observations

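The gene groups in this part were put together after the data had been seen, so their values describe these 2 arrays. Type I interferon genes were themselves higher in the sample labelled HES1: 11 of 12 measured were at least 2-fold higher by their measured signals (9 by bounds), with a median log2 difference of 2.99 (1.72 under the normexp correction). Ifnb1, which encodes interferon beta, was not well above background in the GFP sample and at least 17.4-fold higher, and Ifna4 at least 22.99-fold higher. The interferon alpha genes are near copies of each other, and their probes cannot be taken as separate measurements. Receptors and receptor kinases of the pathway were level (7 measured, 0 past 2-fold), with Ifnar1 at -0.18, Ifnar2 at 0.35 and Jak1 at 0.03. Of 11 genes that sense or respond to viral nucleic acid, 7 were at least 2-fold higher. They included Zbp1 (231-fold), Dhx58 (60.6-fold) and Tlr3 (51.7-fold), whereas the adaptors Mavs and Sting1 were at -0.35 and 0.04. All 13 measured genes of a list for MHC class I presentation were at least 2-fold higher, 4 of which are also in the interferon list. H2-K1 was 22.7-fold higher and its transactivator Nlrc5 32.1-fold. Of 5 MHC class II genes 1 passed 2-fold, and the class II transactivator Ciita was at -0.23.

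Within the unfolded protein response list, 7 genes of the ATF4 branch had a median of 2.48. Another 15, chaperones and other endoplasmic reticulum folding genes, had a median of 0.27, at the 99.63th percentile of random lists, with 0 past 2-fold. Hspa5, which encodes the chaperone BiP, was at 0.97 and Hsp90b1 at -0.03. The split was made after the values were seen, and the list's 5 genes past 2-fold all fell in the ATF4 group. The 0 in the other group followed from that, so the contrast is no separate finding. A chosen group of ERK signalling outputs was higher (11 measured, 6 past 2-fold, median 1.29, 0.90 under normexp), and 7 of them are also in the FGF or immediate early lists. The largest in the group were Egr1 and Fosl1 (9.59-fold). The group does not hold every such gene. Spry1 at -0.12 and Dusp7 at -0.69 were left out, as was Fos, which was higher at 3.58. A chosen group of Wnt feedback targets was lower (11 measured, 5 past 2-fold, median -0.85, -0.57 under normexp). Those past 2-fold were Axin2, Nkd1, Lgr5, Wif1 (2.53-fold) and Lgr4 (2.05-fold), and all of them are also in the Wnt list, as are Tcf7, Nkd2 and Lef1. The group is therefore no separate finding from that list. Its members outside the Wnt list lay within 2-fold: Rnf43 at -0.66, Znrf3 at -0.24 and Notum at -0.15. Lef1 was at 0.23. The group does not hold every such target, and Dkk1 (0.69) and Ccn4 (0.30) of the Wnt list were left out. Of 18 measured clade B serpins, which inhibit proteases inside cells, 10 were higher (9 by bounds) and 0 lower, with a median of 2.25 that was 1.14 with genes on 1 array set to their bounds and 0.73 under normexp. The Serpinb9 family stood out, from Serpinb9 at 9.35-fold to Serpinb9c at 25.2-fold, with near copies among its members. In the HOX list, the 8 measured Hoxb genes all lay within 2-fold, with a median of 0.49 and a range from -0.08 to 0.79. The 10 Hoxa genes had a median of -0.50 (from -1.16 to 0.04), the 5 Hoxc genes -1.03 (from -1.47 to 2.02) and the 4 Hoxd genes -0.77 (from -1.07 to -0.35). A difference between the clusters was not tested. Relative to the median of all genes, each of these 4 medians kept its sign under the quantile, loess and normexp normalizations.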
